A study of Homo sapiens with 24 samples.

How the data were processed

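Gene expression was measured on 24 Illumina expression beadchip arrays, 1 per culture, in 8 groups of 3. The series describes the 3 cultures of each treatment as biological triplicates. Groups were taken from the sample titles and treatment labels, which give the doses of dihydrotestosterone (DHT, 1 nM) and dexamethasone (Dex, 10 and 100 nM). They give 10 µM for enzalutamide alone and no enzalutamide dose for the combinations.

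The deposited signal intensity of each probe is the mean bead signal, without normalization between arrays, per the file headers. The deposited detection p-value of each probe compares that signal with the negative control beads of the same array, per the file headers. Bead numbers and the standard error over beads come with each signal, per the file headers. GenomeStudio made these values, per the submitters' processing notes; its version is not given in the sources used here. A deposited table of normalized intensity values for the same arrays states no method. Its values ranked the probes of each array exactly as the signals did (Spearman rho of 1 on every array), lay on a linear scale, were below 0 for 29.4% to 29.6% of probes, and had medians from 9.29 to 9.33 on the 24 arrays. Background subtraction and quantile normalization give that pattern, and the method itself stays unknown. These values served as an alternative only.

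Each array held 47323 probes. Of these, 30113 had 1 gene symbol in the platform annotation, 8 had several and 17202 had none; the unnamed ones are unnamed here and not necessarily without a gene. Symbols were looked up by Entrez identifier in a RefSeq table of GRCh38.p14, which matched 30074 probes and changed 0 symbols. Array coordinates are not given because no genome build was used for the probes.

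Signals were background-corrected by normexp with negative-control parameters inferred from the detection p-values, with an offset of 16, then quantile normalized and put on the log2 scale (limma 3.58.1 in R 4.3.3). Probes with a detection p under 0.05 on at least 3 arrays were kept: 24607 probes, of which 17590 had 1 symbol. A gene with several kept probes (3586 genes) was represented by the probe with the highest mean over the 24 arrays, which left 12895 genes. A linear model of 8 group means was fitted to all 24 arrays (lmFit and eBayes), and p-values were adjusted by Benjamini-Hochberg within each comparison. A gene is called where its adjusted p is under 0.05. All adjusted p-values of genes are from this limma fit, and values after ± are standard errors of a log2 change over 3 arrays per group unless named as SD. There were 12 pairwise comparisons and 4 differences of enzalutamide effects. A gene not detected on any of the 3 arrays of a group has only a bound: the brighter group's mean was set against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own signal, and is given as "at least N-fold". Probes are compared with themselves across groups and never with other probes. A gene counts as detected on an array where any of its probes is, which need not be the probe whose change is given.

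These choices, the gene lists and the rule for named genes were made before the data were examined. The rule takes, from genes called with no overlap between both groups' arrays (a separation that 10% of 3-against-3 draws give by chance), the 10 largest rises and 10 largest falls for DHT vs vehicle, Dex 100 nM vs vehicle and enzalutamide against each of them, and 5 each way elsewhere. It adds a fixed set of androgen and glucocorticoid response genes, not all of which are analysed here, and up to 4 called members of each list.

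Of 24 gene lists, 21 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 252 tests (21 lists in 12 comparisons); the same test was repeated with the correlation estimated from the data. The lists were androgen-induced, androgen-repressed and glucocorticoid-induced genes, metallothioneins, circadian clock, sterol and fatty acid synthesis, endoplasmic reticulum folding and unfolded protein response, polyamine synthesis, amino acid and glucose uptake with glycolysis, S phase, mitosis, MYC and ribosome biogenesis, NF-kB and cytokines, immediate early genes and MAPK feedback, steroid metabolism, steroid receptors and cofactors, interferon response, heat shock and p53 stress, hypoxia, luminal epithelium, and stroma with endothelium. The basal epithelium, neuroendocrine and immune lists had only 3, 3 and 4 measured members and none was called in any pairwise comparison.

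The procedure was tested on simulated bead signals for DHT vs vehicle with 18019 genes. It recovered 44% of genes changed 1.25-fold, 80% of those changed 1.5-fold and all of those changed 2-fold or 4-fold. Changes were planted only in brighter genes, so these rates do not cover genes near the detection limit. In the simulation 13 of 174 calls were false (7.47%), and 11 comparisons of unchanged groups gave at most 1 call each.

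The alternatives were no background correction, median scaling, the deposited normalized values (floored at 16), no filter or a stricter filter on dim probes (detection p under 0.01 on all 3 arrays of a group), the mean of a gene's probes, every probe alone, array weights, an intensity trend, a block for runs of sample numbers, only the groups compared, a 1.5-fold minimum and leaving out each array. Median scaling over the genes tested, robust eBayes and leaving out the pair of arrays with the most deviating genes were added after the data were seen. A block by chip was not run, since the files used here name no chips. XIST and Y-linked genes are not reported.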

Results

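Expression was profiled in LREX' cells, a human prostate cancer line that keeps growing under the antiandrogen enzalutamide and holds a high level of the glucocorticoid receptor. The cells were kept in medium stripped of steroids and treated for 8 h with vehicle, the androgen DHT (1 nM), the synthetic glucocorticoid dexamethasone (10 or 100 nM), enzalutamide, or enzalutamide with each of these steroids. Each of the 8 groups held 3 arrays, and this number limits the precision. Median signals ran from 59.4 to 69.5 over the 24 arrays, with 19463 to 21017 probes detected and a median of 18 to 21 beads per probe. Arrays of one group correlated at 0.992 to 0.995 across genes, and the median standard error of a log2 change was 0.12. The design asks which genes either hormone regulates in these cells, and which of the responses enzalutamide blocks.

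DHT raised several classical androgen targets. SLC45A3, a prostate solute carrier, rose 6.36-fold (log2 2.67 ± 0.07, n = 3 arrays per group, limma adjusted p = 1.06e-15), and TMPRSS2, the androgen-regulated membrane protease, rose 4.93-fold (log2 2.30 ± 0.11). KLK2, a secreted prostate kallikrein, was not detected with vehicle and rose at least 3.47-fold. KLK3, the prostate-specific antigen gene, was not called with DHT (log2 0.67 ± 0.26, at least 1.16-fold, limma adjusted p = 0.223). It lay near background, detected on 2 of 3 DHT arrays and not with vehicle. The largest rise was that of SGK1, a kinase that promotes sodium uptake and cell survival, by 3.46 ± 0.12 on the log2 scale (adjusted p = 8.42e-14), followed by RASD1, a small GTPase first described as dexamethasone-induced (8.45-fold), and RHOU, an atypical GTPase (7.86-fold). FKBP5, a chaperone partner of steroid receptors, rose 2.73-fold.

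Among the other large rises with DHT were PMEPA1, a TGF-beta feedback inhibitor detected on 2 of the 3 vehicle arrays (log2 2.38 ± 0.14), and ERRFI1, an inhibitor of the EGF receptor (4.31-fold). The metastasis suppressor NDRG1 rose 4.09-fold, and the epithelial transcription factor GRHL2 rose 2.66-fold. SNAI2, a transcriptional repressor of epithelial genes, was not detected with vehicle and rose at least 2.65-fold. The largest falls were in LIPG, the endothelial lipase (2.93-fold, log2 -1.55 ± 0.07), NAPEPLD, which makes N-acylethanolamines (2.62-fold), and SYTL2, a vesicle-docking protein (2.40-fold). The neurotrophin BDNF fell 2.37-fold, and the TGF-beta pseudoreceptor BAMBI fell 2.13-fold. GCNT3, detected on 2 of the 3 DHT arrays (log2 -1.19 ± 0.17), LTN1, NR4A2, MUC13 and PCED1B also fell. NR3C1, which encodes the glucocorticoid receptor, fell 2.01-fold (log2 -1.01 ± 0.19, adjusted p = 0.00205). That value comes from 1 of its probes, and the other probe past the detection filter moved by -0.07 ± 0.16.

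In all, 549 of 12895 genes were called with DHT, 316 higher and 233 lower, with 233 of them changed at least 1.5-fold. Of 25 androgen-induced genes, 14 rose and none fell (21 rose when adjusted over the list alone; median log2 1.21, camera adjusted p = 8.24e-48). Of 12 androgen-repressed genes 5 fell, among them the kinase inhibitor CAMK2N1 (log2 -0.60 ± 0.08), with 7 falling when adjusted over the list alone (adjusted p = 1.2e-05). The glucocorticoid-induced list also rose with DHT, 11 of 27 genes higher (12 higher and 1 lower when adjusted over the list alone; adjusted p = 4.96e-23), including TIPARP, a mono-ADP-ribosyltransferase (3.92-fold), and CEBPD, an acute-phase transcription factor (2.92-fold). The uptake and glycolysis list held 3 rises of 20 genes (3 also when adjusted over the list alone), led by the glucose transporters SLC2A12 (2.66-fold) and SLC2A3 (at least 2.24-fold); its adjusted p was 0.00218, and 0.0553 with an estimated correlation. The remaining 17 lists did not pass the test (adjusted p from 0.0709 to 0.998); in the NF-kB, steroid receptor, heat shock and hypoxia lists the median and mean differed in sign. Over all 12 comparisons 53 of 252 list tests passed, and 32 of these hold with an estimated correlation; each of the others is given with both values. Of the 58 called genes the naming rule took here, 11 lost their call when 1 array was left out; no gene named above is among them. With median scaling over all probes the calls split into 206 higher and 234 lower, and with only the 6 arrays compared in the fit 290 genes were called.

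Among the steroids given without enzalutamide, dexamethasone at 100 nM gave the largest change of a single gene. SGK1 rose 65.6-fold (log2 6.04 ± 0.12, n = 3 arrays per group, adjusted p = 7.19e-18). ZBTB16, a zinc-finger repressor long known as a glucocorticoid target, rose by 2.95 ± 0.13 on the log2 scale. The gene was detected on 1 of 3 vehicle arrays, but not by the probe that gave this change. That probe averaged 4.66 (SD 0.09) with vehicle, under the lowest detected signals of those arrays (4.99 to 5.04). The size of the rise is therefore uncertain. ERRFI1 rose 6.28-fold and FKBP5 rose 4.24-fold. PER1, a clock gene with glucocorticoid response elements, was not detected with vehicle and rose at least 2.03-fold (adjusted p = 0.000464). TSC22D3, also called GILZ, rose 1.54-fold. The steroid-inactivating enzyme HSD11B2 rose 2.29-fold, and DUSP1, a MAPK phosphatase, rose 1.58-fold.

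Androgen targets rose with dexamethasone too. SLC45A3 was higher 4.73-fold, KLK4 3.06-fold, TMPRSS2 2.59-fold (log2 1.37 ± 0.11) and KLK2 at least 2.49-fold. KLK3, which encodes prostate-specific antigen, lay near background: it was detected on 2 of 3 arrays with Dex 100 nM and on none with vehicle (at least 1.49-fold, adjusted p = 0.0234). Its call was lost when any of 5 of the 6 arrays was left out (adjusted p from 0.056 to 0.113). The largest falls with Dex 100 nM were in SYTL2 (2.47-fold) and NR3C1 (2.47-fold, log2 -1.30 ± 0.19), again on 1 of its probes. The nuclear receptor NR4A2 fell 2.07-fold, the kinase MAP3K8 fell 1.94-fold, BAMBI fell 1.93-fold and GASK1B fell 1.97-fold. WNK3, detected on 2 of 3 arrays with Dex 100 nM, fell by 1.00 ± 0.21 on the log2 scale. The osmotic stress factor NFAT5 (log2 -1.05 ± 0.30) and the inositol transporter SLC5A3 (log2 -0.99 ± 0.26) leaned on Dex 100 nM replicate 2, without which they were -0.46 (adjusted p = 0.0871) and -0.64 (adjusted p = 0.185). Leaving out any vehicle array ended both calls too (adjusted p from 0.0542 to 0.129). The SD of the 3 Dex 100 nM arrays was 1.03 for NFAT5 and 0.62 for SLC5A3, which the ± values do not show.

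With Dex 100 nM 653 genes were called, 371 higher and 282 lower. With only the 6 arrays compared in the fit there were 277; leaving out replicate 2 of this group gave 464, of which 433 were among the 653. Of the 62 called genes that the naming rule took here, 18 lost their call when 1 array was left out; of those named here, these are KLK3, NFAT5 and SLC5A3. Of 27 glucocorticoid-induced genes 19 rose (20 when adjusted over the list alone; median log2 0.75, adjusted p = 1.02e-44), and of 25 androgen-induced genes 16 rose (18 when adjusted over the list alone; adjusted p = 5.92e-35). Of 5 metallothioneins, metal-binding proteins, 2 rose, led by MT1X at 1.64-fold (3 when adjusted over the list alone; list adjusted p = 0.000517). The circadian clock list rose, 6 of 16 genes higher (9 higher and 1 lower when adjusted over the list alone; adjusted p = 2.18e-05), with CRY2 2.28-fold and PER2 1.74-fold higher. Endoplasmic reticulum folding (2 of 21 genes higher, 3 when adjusted over the list alone; adjusted p = 0.0147), MAPK feedback (3 of 16 higher and 1 lower, the same when adjusted over the list alone; adjusted p = 0.0119) and steroid metabolism (2 of 15 higher, 3 when adjusted over the list alone; adjusted p = 0.00581) also rose. The uptake list (4 of 20 higher, the same when adjusted over the list alone; adjusted p = 0.00992, and 0.0957 with an estimated correlation) rose and the mitosis list (3 of 26 lower and 1 higher, 4 and 1 when adjusted over the list alone; adjusted p = 0.0493, and 0.2 with an estimated correlation) fell only with the preset correlation. The other 12 lists gave adjusted p-values from 0.105 to 0.998, with the median and mean of the steroid receptor, interferon and hypoxia lists differing in sign. Stroma and endothelium markers were among these, with ACTA2, smooth muscle actin, 2.83-fold higher and VWF 1.38-fold lower.

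**Figure D1:**
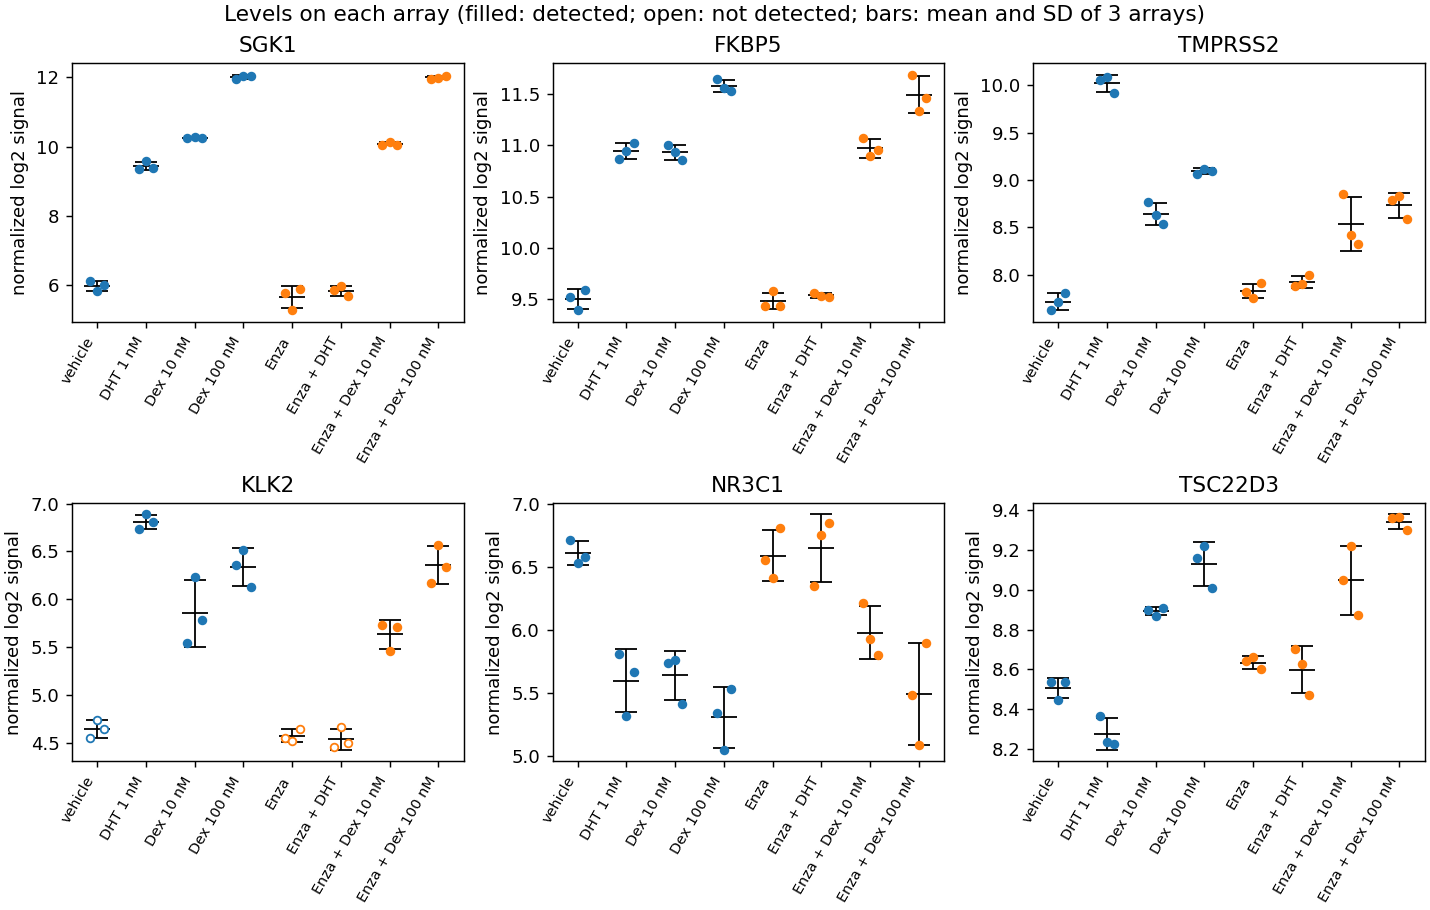
Normalized log2 signal of SGK1, FKBP5, TMPRSS2, KLK2, NR3C1 and TSC22D3 on each of the 24 arrays (y axes), by group (x axes). Points are arrays, open where the gene was not detected, and bars give the mean and SD of 3 arrays; SGK1 rises by 3.46 with DHT and by 6.04 with Dex 100 nM, and enzalutamide removes the first rise.

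Many of the genes called at 100 nM were called at 10 nM dexamethasone too. SGK1 rose 19.5-fold (log2 4.28 ± 0.12), FKBP5 2.70-fold, TMPRSS2 1.90-fold and KLK2 at least 1.79-fold, and NR3C1 fell 1.96-fold (adjusted p = 0.0065). ZBTB16 (log2 2.50 ± 0.13) and SPSB1, a ubiquitin-ligase adaptor (4.33-fold), were among the largest rises, and SYTL2 (1.71-fold) and STYXL2, not detected with Dex 10 nM (at least 1.70-fold), among the largest falls. The vehicle values of this ZBTB16 probe lay below detection, as given above. In total 283 genes were called, 175 higher and 108 lower, and 231 of these were also called with Dex 100 nM, all in the same direction. Both comparisons use the vehicle arrays, so part of this agreement may come from the shared arrays. Leaving out vehicle replicate 1 or 3 gave 183 or 176 calls, and leaving out Dex 10 nM replicate 2 or 3 gave 186 or 180; with only the 6 arrays compared in the fit there were 102. Median scaling over all probes shifted the median of all genes by -0.12 here and gave 105 higher and 447 lower, whereas median scaling over the genes tested gave 244 higher and 85 lower.

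The list results at 10 nM resembled those at 100 nM in direction. Of 25 androgen-induced genes 12 rose (16 when adjusted over the list alone; adjusted p = 1.32e-28), and of 27 glucocorticoid-induced genes 15 rose (16 when adjusted over the list alone; adjusted p = 1.76e-30). Metallothioneins (2 of 5 higher, 3 when adjusted over the list alone; adjusted p = 4.75e-05) and clock genes (6 of 16 higher, 9 with 3 lower when adjusted over the list alone; adjusted p = 9.7e-06) rose. With an estimated correlation, calls were lost for androgen-repressed genes (none of 12 called, 3 lower when adjusted over the list alone; adjusted p = 0.0363, and adjusted p = 0.0874 with an estimated correlation), endoplasmic reticulum folding (higher, 0.0297 and then 0.0554), uptake and glycolysis (higher, 0.00382 and then 0.0644), mitosis (lower, 0.0297 and then 0.167) and luminal markers (higher, 0.0493 and then 0.0899). The other 12 lists gave adjusted p-values from 0.122 to 0.998, and median, mean and test differed in sign for the sterol, steroid receptor, interferon, heat shock and hypoxia lists.

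Between the doses, 75 genes were higher and 9 lower at 100 nM. SGK1 was 3.37-fold higher at 100 nM (log2 1.75 ± 0.12, adjusted p = 2.99e-08), ERRFI1 2.36-fold, RASD1 2.41-fold and ACTA2 2.02-fold. SNAI2, detected on 2 of 3 arrays at 10 nM, was higher by 1.69 ± 0.08 on the log2 scale. The SNAI2 probe that gave this change averaged 4.96 (SD 0.07) at 10 nM, under the lowest detected signals of those arrays (5.03 to 5.07). The size of this difference is therefore uncertain. Androgen-induced genes (5 of 25 higher, 13 when adjusted over the list alone; adjusted p = 2.27e-17) and glucocorticoid-induced genes (12 of 27, 16 when adjusted over the list alone; adjusted p = 4.4e-29) were higher at 100 nM. MAPK feedback (adjusted p = 0.0349) and steroid metabolism (adjusted p = 0.0307) passed only with the preset correlation (adjusted p = 0.0644 and 0.0641 with an estimated correlation), and the other 17 lists did not pass. KLK2 (log2 0.48 ± 0.14, adjusted p = 0.209) and TMPRSS2 (log2 0.45 ± 0.11, adjusted p = 0.0687) did not pass. Over the 653 genes called at 100 nM, the 10 nM change was a median 0.62 of the 100 nM change, with 645 in the same direction. Picking genes by their 100 nM change lowers this share. Both changes use the same vehicle arrays, which favours agreement in direction. Leaving out Dex 100 nM replicate 2 gave 45 calls between the doses, 44 of them shared with the 84, and leaving out Dex 10 nM replicate 3 gave 53. A fit of only the 6 arrays compared gave 14. The 5 falls that the naming rule took here all lost their calls when 1 array was left out.

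Enzalutamide alone changed none of the leading androgen targets past the test. FKBP5 (log2 -0.02 ± 0.08), TMPRSS2 (0.11 ± 0.11) and NR3C1 (-0.02 ± 0.19) did not pass, nor did SGK1 (-0.33 ± 0.12, 95% interval -0.57 to -0.09, adjusted p = 0.535), whose interval leaves room for a fall. KLK2 and KLK3 were not detected in either group, so a change in them could not be seen. Only 2 genes were called, both lower: PATE1, an acrosomal protein gene that was not detected with enzalutamide (at least 1.42-fold lower, adjusted p = 0.0481), and ASF1A, a histone chaperone (log2 -0.44 ± 0.07, adjusted p = 0.0481). The call of PATE1 was lost without any 1 of the 6 arrays (adjusted p from 0.0806 to 0.325), and that of ASF1A without any but vehicle replicate 1 (0.148 to 0.325). At an unadjusted p under 0.05 there were 1006 genes, more than the 0.05 of 12895 expected with no change, and no list passed.

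With DHT present, enzalutamide lowered the genes that DHT had raised most. SGK1 fell 12.1-fold (log2 -3.60 ± 0.12, n = 3 arrays per group, adjusted p = 4e-14), RASD1 7.56-fold, RHOU 7.03-fold, SLC45A3 5.55-fold and TMPRSS2 4.27-fold (log2 -2.10 ± 0.11). KLK2 and SNAI2 were not detected with the combination and fell at least 3.48-fold and at least 2.66-fold. PMEPA1 (log2 -2.42 ± 0.14) and ZBTB16 (log2 -2.01 ± 0.13) were each detected on 1 of 3 arrays with the combination. The ZBTB16 probe that gave this change averaged 4.56 (SD 0.10) there, under the lowest detected signals of those arrays (4.97 to 5.06). The size of the ZBTB16 fall is therefore uncertain. FKBP5 fell 2.66-fold, and NDRG1, GRHL2 and TIPARP fell 3.69-fold, 2.91-fold and 3.88-fold. Genes that DHT had lowered rose: LIPG 2.35-fold, NAPEPLD 2.29-fold, BDNF 2.07-fold, BAMBI 2.05-fold and NR4A2 2.04-fold. NR3C1 rose 2.07-fold (log2 1.05 ± 0.19, adjusted p = 0.00155).

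Here 480 genes were called, 157 higher and 323 lower, and 233 with only the 6 arrays compared in the fit. Of them 364 were also called with DHT, all in the opposite direction; both comparisons use the DHT arrays, so part of this opposition may come from the shared arrays. Androgen-induced genes fell (16 of 25, 19 when adjusted over the list alone; adjusted p = 8.24e-48), androgen-repressed genes rose (5 of 12, 6 when adjusted over the list alone; adjusted p = 2.18e-05) and glucocorticoid-induced genes fell (11 of 27 with 1 higher, 13 and 1 when adjusted over the list alone; adjusted p = 1.63e-20). The clock (2 of 16 lower; adjusted p = 0.0147), sterol and fatty acid (1 of 24; 0.0196), polyamine (2 of 10; 0.0419) and uptake lists (3 of 20; 0.00607) fell with the preset correlation (5, 6, 2 and 4 lower when adjusted over the list alone, with 1 clock gene higher), and gave adjusted p = 0.158, 0.0641, 0.0855 and 0.0806 with an estimated correlation. Across the 549 DHT genes, the change left under enzalutamide was a median 0.026 of the change without it, and 312 had the same direction. Against enzalutamide alone, enzalutamide with DHT gave 0 called genes by limma, and no list passed. At an unadjusted p under 0.05 there were 428, fewer than the 0.05 of 12895 genes expected with no change. The test of the difference itself called 233 genes, 70 with a positive and 163 with a negative interaction. They included SGK1 (-3.27 ± 0.16), SLC45A3 (-2.49 ± 0.09), TMPRSS2 (-2.21 ± 0.15) and FKBP5 (-1.39 ± 0.12).

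With dexamethasone present, enzalutamide changed no single gene past the test. At Dex 100 nM, SGK1 differed by -0.01 ± 0.12 between the arrays with and without enzalutamide, FKBP5 by -0.09 ± 0.08, KLK2 by 0.03 ± 0.14 and TMPRSS2 by -0.36 ± 0.11 (adjusted p = 0.399). At Dex 10 nM the values were -0.17 ± 0.12 for SGK1, 0.04 ± 0.08 for FKBP5, -0.22 ± 0.14 for KLK2 and -0.11 ± 0.11 for TMPRSS2. Both comparisons gave 0 called genes by limma, with 1050 genes at Dex 100 nM and 900 at Dex 10 nM at an unadjusted p under 0.05. The interaction tests against enzalutamide alone also gave 0, with 981 and 1003 genes. Each of these counts at an unadjusted p under 0.05 exceeded the 0.05 of 12895 genes expected with no change. The androgen-induced list was lower with enzalutamide at Dex 100 nM by a median log2 of -0.08 (none of 25 genes called, 2 lower when adjusted over the list alone; adjusted p = 0.0113, and 0.0341 with an estimated correlation). The glucocorticoid-induced list was lower by -0.06 (adjusted p = 0.0419, and adjusted p = 0.116 with an estimated correlation). At Dex 10 nM the stroma and endothelium list was lower by -0.19 with none of 9 genes called (adjusted p = 0.0113, and 0.0374 with an estimated correlation).

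Dexamethasone kept much of its effect in the presence of enzalutamide. With enzalutamide and Dex 100 nM against enzalutamide alone, SGK1 rose 81.6-fold (log2 6.35 ± 0.12), ERRFI1 5.17-fold, FKBP5 4.05-fold, SLC45A3 3.62-fold, KLK2 at least 2.52-fold and TMPRSS2 1.87-fold, while NR3C1 fell 2.14-fold (adjusted p = 0.00105). The neuronal membrane protein gene LRRN1 fell 1.98-fold, MAP3K8 fell 1.83-fold and VWF was lower by a log2 of -0.59 ± 0.10. KLK3, near background, was not called (log2 0.41 ± 0.26, adjusted p = 0.537). In total 439 genes were called, 287 higher and 152 lower (168 with only the 6 arrays compared in the fit). At Dex 10 nM there were 139, 115 higher and 24 lower (57 in such a fit), with SGK1 21.6-fold, FKBP5 2.81-fold and TMPRSS2 1.63-fold higher and BDNF lower by a log2 of -0.58 ± 0.09. Median scaling over all probes gave 127 higher and 3 lower for this comparison.

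Over the genes called without enzalutamide, a median 0.70 of the Dex 100 nM change and 0.64 of the Dex 10 nM change remained under it. Of these genes 608 of 653 and 253 of 283 kept their direction, and 296 and 109 were called again. Picking genes by their change without enzalutamide lowers these shares; over genes changed at least 1.5-fold they were 0.83 and 0.84. Under median scaling over all probes the Dex 10 nM share was 0.071, where the median of all genes moved by 0.11 in enzalutamide with Dex 10 nM against Dex 10 nM and by 0.18 in the interaction; with median scaling over the genes tested it was 0.57. The enzalutamide effect with Dex 100 nM differed from that with DHT for 209 genes (126 with only the 12 arrays compared in the fit), among them SGK1 (difference 3.58 ± 0.16), RHOU (2.72 ± 0.12), KLK2 (2.30 ± 0.20) and TMPRSS2 (1.74 ± 0.15).

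Androgen-induced (13 of 25 genes higher, 15 when adjusted over the list alone; adjusted p = 5.89e-36) and glucocorticoid-induced genes (18 of 27, 20 when adjusted over the list alone; adjusted p = 7.43e-44) rose with Dex 100 nM under enzalutamide, as did steroid metabolism genes (2 of 15, adjusted p = 0.00813), led by HSD11B2 at 2.16-fold. The clock list (4 of 16 higher, adjusted p = 0.00248, and 0.0957 with an estimated correlation), the uptake list (2 of 20, 0.0249 and then 0.134) and MAPK feedback (3 of 16, 0.0237 and then 0.0544; its median was -0.01 and its mean 0.22) passed only with the preset correlation. At Dex 10 nM the same 3 lists rose: androgen-induced (12 of 25, 14 when adjusted over the list alone; adjusted p = 6.51e-30), glucocorticoid-induced (13 of 27, 14 with 1 lower when adjusted over the list alone; adjusted p = 4.45e-32) and steroid metabolism (2 of 15, adjusted p = 0.00296). Clock genes (adjusted p = 0.000571, and 0.0644 with an estimated correlation) and uptake (0.0166 and then 0.117) passed only with the preset correlation.

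**Figure D2:**
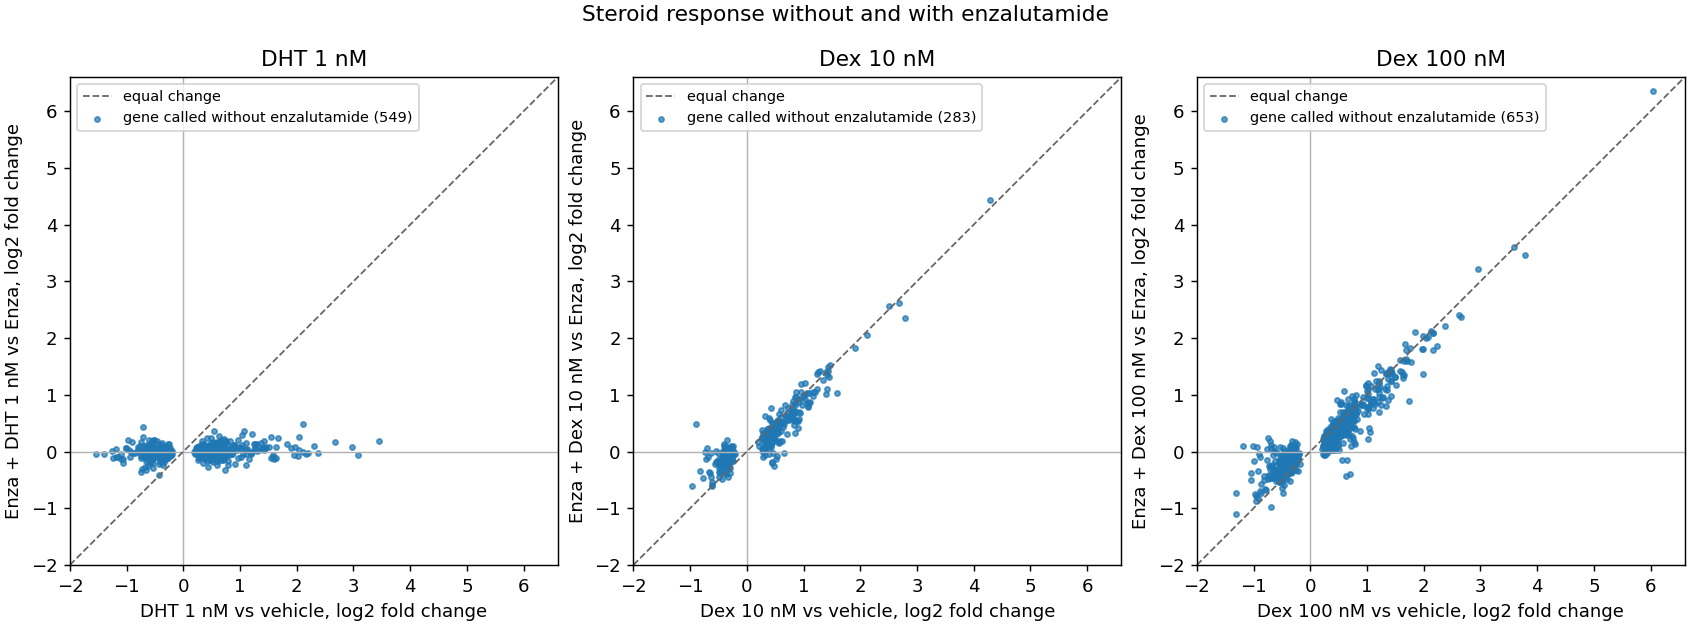
Log2 fold change of each gene called with a steroid, without enzalutamide (x axes) and with it (y axes); each point is a gene and the dashed line marks equal change. The 549 DHT genes lie along 0 on the y axis (median share 0.026), and the 283 and 653 Dex genes keep part of their change, with median shares of 0.64 and 0.70 and lower quartiles of 0.28 and 0.40.

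DHT and dexamethasone, steroids that differ in side chain, unsaturation and a fluorine, were given at different doses, so their values stand side by side. Of the genes called, 169 rose and 122 fell with each, against 9.09 and 5.10 for independent lists of these sizes; called with DHT only were 147 higher and 109 lower genes, and with Dex 100 nM only 200 and 160. Simulated unchanged groups against the same vehicle arrays shared at most 1 call in 100 simulations, but such groups give few calls at all, so this does not measure what the shared arrays add. Across all genes the changes correlated at 0.646 (0.499 in simulations, from the shared vehicle arrays), with a covariance of 0.0361 against 0.0113 simulated, a difference of 0.0247. The 3 vehicle arrays cannot be split with at least 2 in each part, so part of the excess in shared calls may come from the shared controls, whose share the difference in covariance leaves out. A comparison that shares no arrays gave a like picture: across the 549 DHT genes, changes with DHT and with Dex 100 nM under enzalutamide correlated at 0.75 (Spearman 0.77, across genes, which are not independent replicates), 456 had the same direction, and 195 were called with it.

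The 2 hormones also differed at these doses. Higher with Dex 100 nM than with DHT were SGK1 (5.97-fold, log2 2.58 ± 0.12, n = 3, limma adjusted p = 5.75e-11), SCNN1G, a subunit of the epithelial sodium channel (5.57-fold), the membrane protein EMP1 (3.68-fold), the keratin KRT80 (3.52-fold), TSC22D3 (1.80-fold) and HSD11B2 (1.82-fold). Higher with DHT were TIPARP (3.17-fold), PRAG1, a pseudokinase (3.01-fold), TMPRSS2 (1.90-fold), SLC2A3 (at least 2.15-fold), the acute-phase protein ORM1 (at least 2.07-fold) and the natriuretic peptide NPPC (at least 1.98-fold). KLK2 (log2 -0.48, 95% interval -0.77 to -0.18, adjusted p = 0.0851), KLK3 (0.36, -0.19 to 0.91) and NR3C1 (-0.29, -0.69 to 0.10) were not called as different. These intervals leave room for a difference. On the 1 probe kept per gene, DDIT4, a stress-induced mTOR inhibitor, and KRT80 were the only genes called in opposite directions. DDIT4 was -0.31 ± 0.08 with DHT and 0.99 ± 0.08 with Dex 100 nM, and KRT80 was -0.69 ± 0.14 and 1.13 ± 0.14. With every probe tested alone, another TSC22D3 probe was also called both ways. It was -0.40 with DHT (limma adjusted p = 0.0133) and 0.71 with Dex 100 nM (adjusted p = 3.51e-05). The kept TSC22D3 probe was -0.23 ± 0.08 with DHT and not called (adjusted p = 0.145). The DHT call of DDIT4 was lost without replicate 1 or 2 of either DHT or vehicle (adjusted p from 0.0592 to 0.153).

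Between Dex 100 nM and DHT 337 genes were called, 192 higher and 145 lower with Dex; without Dex 100 nM replicate 2 there were 208, of which 197 were among the 337, and with only the 6 arrays compared in the fit there were 120. Androgen-induced genes were lower with Dex (7 of 25 lower and 2 higher, 11 and 4 when adjusted over the list alone; adjusted p = 0.00813), including C1orf116 and GRHL2, and androgen-repressed genes were higher (2 of 12, 3 when adjusted over the list alone; adjusted p = 0.00705). Glucocorticoid-induced genes (15 of 27 higher and 1 lower, 17 and 3 when adjusted over the list alone; adjusted p = 8.67e-19), metallothioneins (2 of 5 higher, 3 when adjusted over the list alone; adjusted p = 0.000304) and steroid metabolism (3 of 15 higher, 4 when adjusted over the list alone; adjusted p = 0.000137) were higher with Dex. So was the clock list with the preset correlation (5 of 16 higher and 1 lower; adjusted p = 0.00467, and 0.116 with an estimated correlation). The other 15 lists did not pass.

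**Figure D3:**
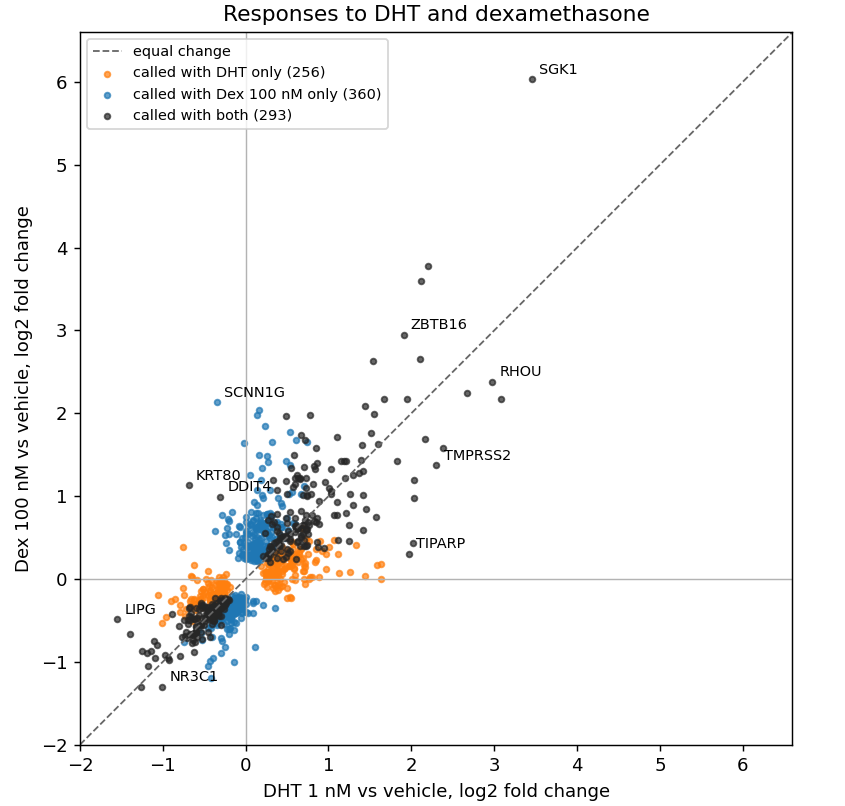
Log2 fold change with DHT (x axis) and with Dex 100 nM (y axis), each against vehicle, for every gene called with either; the dashed line marks equal change. Called with both are 293 genes, 291 of them in the same direction; SCNN1G, KRT80 and DDIT4 rise with Dex 100 nM and lie below 0 with DHT, where the value of SCNN1G (-0.35) did not pass the test.

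**Figure D4:**
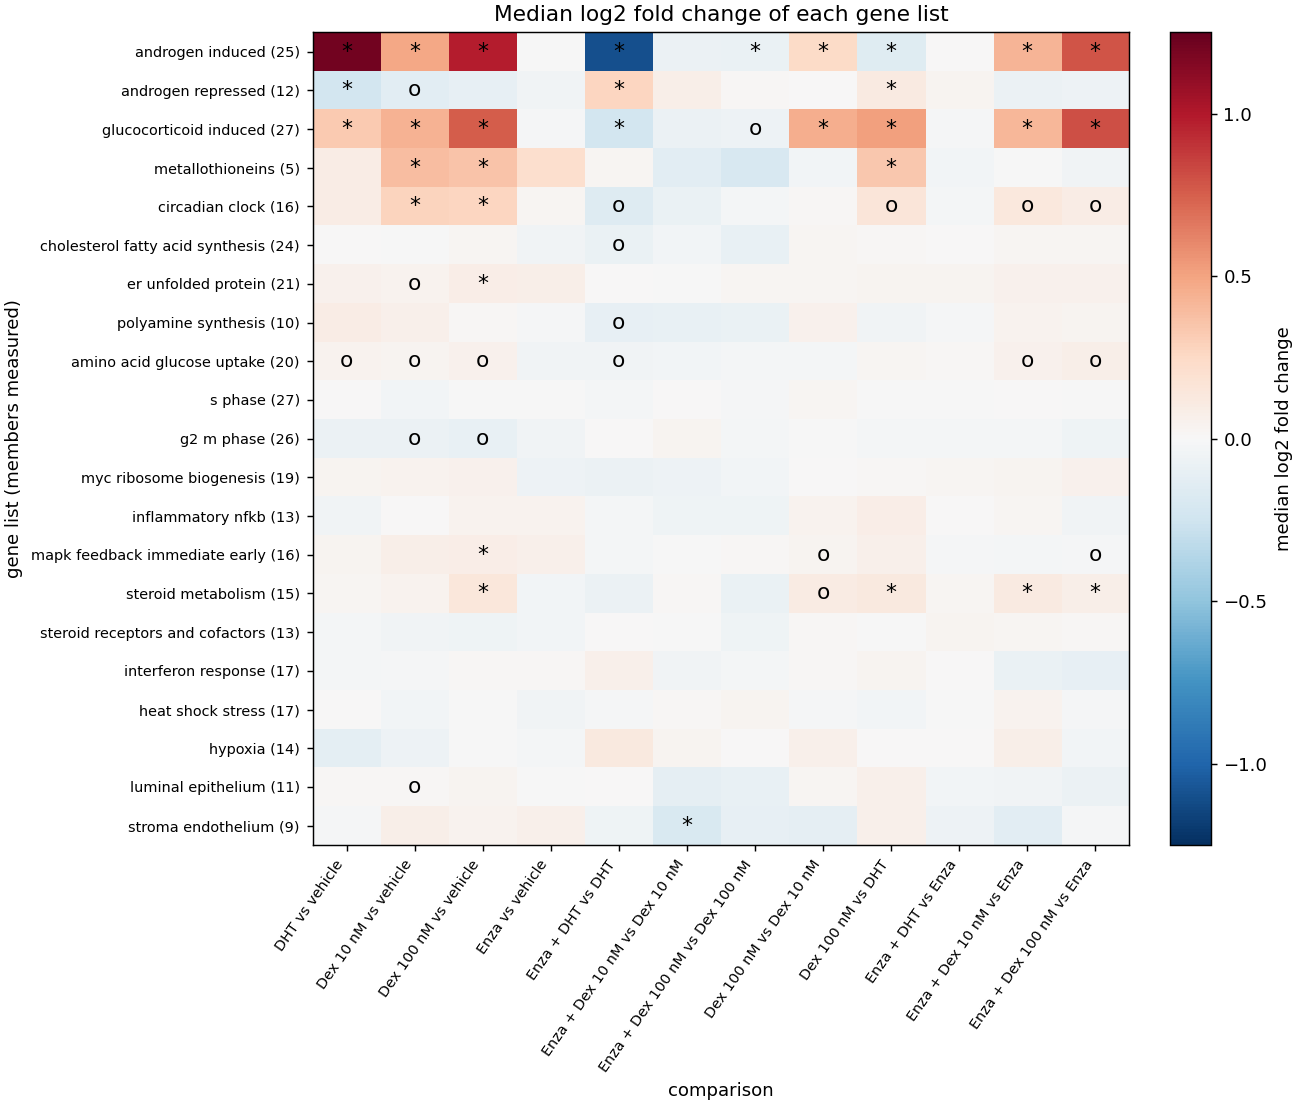
Median log2 fold change (colour) of each of 21 gene lists (y axis, members measured in brackets) in the 12 comparisons (x axis). Stars mark lists past the camera test with the preset and the estimated correlation, and circles those past it with the preset one alone; the androgen-induced row runs from 1.21 with DHT to -1.10 when enzalutamide is added to it.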

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

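For these results, the tests of hybridisation and of the run of sample numbers for the array that stands apart, both tests of Dex against DHT, and those of the androgen-induced list for 1 array and for the pathway that enzalutamide blocks were chosen after the values had been seen.

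The effect of enzalutamide differed between groups. With DHT it differed from that without steroid for 233 genes by the interaction test, and with DHT from that with Dex 100 nM for 209 genes. The largest differences, with Dex 100 nM minus with DHT on the log2 scale, were 3.58 for SGK1, 2.76 for RASD1, 2.72 for RHOU, 2.30 for KLK2 and 2.26 for PMEPA1. In the other direction they were -1.39 for LIPG, -1.14 for NAPEPLD, -1.09 for ST8SIA4, -1.06 for BASP1 and -1.05 for RBBP8NL. ST8SIA4, BASP1 and RBBP8NL lost their calls when single arrays were left out, with adjusted p from 0.053 to 0.127 for ST8SIA4 and from 0.063 to 0.125 for BASP1. RBBP8NL did so without Dex 100 nM replicate 3, enzalutamide with Dex 100 nM replicate 1 or enzalutamide with DHT replicate 3 (0.0569 to 0.059).

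Probes without 1 gene name, outside the comparisons above, held further signal: 52 of 7017 were called with DHT and 54 with Dex 100 nM by limma. Among them ILMN_1776181 rose by 1.88 ± 0.13 and ILMN_3237897 by 1.81 ± 0.15 on the log2 scale with Dex 100 nM. ILMN_1682929 fell by 1.37 and ILMN_2235851 fell by 1.12.

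Other splits of the same arrays were refitted for each count of called genes. In the pairwise comparisons, 6 arrays give only 10 splits, too few for a share under 0.05. The other splits mix arrays of both groups, so a real change widens the spread within each part and lowers their counts. Low counts in them do not measure what unchanged groups would give. The real and highest other counts were 549 and 2 for DHT vs vehicle, 283 and 0 for Dex 10 nM, 653 and 1 for Dex 100 nM, 2 and 1 for enzalutamide, and 480 and 1 for enzalutamide with DHT against DHT. In each of these 1 split, the real one, reached the count. They were 84 and 0 between the Dex doses, 337 and 2 for Dex 100 nM against DHT, 139 and 0 for enzalutamide with Dex 10 nM against enzalutamide, and 439 and 2 with Dex 100 nM, again with 1 split each. Where the real count was 0, all 10 splits reached it, and the highest other counts were 0 (enzalutamide with Dex 10 nM against Dex 10 nM), 1 (the same at 100 nM) and 1 (enzalutamide with DHT against enzalutamide). For the DHT interaction, 1 of 100 assignments of its 12 arrays reached 233 (highest other 221), and for the difference between Dex 100 nM and DHT 1 of 100 reached 209 (highest other 182). The other assignments mix arrays with and without steroid and come close to the real counts, so this rank is no test against the absence of an interaction. Both Dex interactions called 0 genes and all 100 assignments reached that; the highest others were 371 and 197, which points to the steroid groups, mixed in such assignments, as a structure of the arrays.

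The array Dex 100 nM replicate 2 carried 231 genes over 0.5 log2 units from their group mean, against a median of 105 and at most 167 on the other arrays. Its signal, detected probes and bead numbers argued against weak hybridisation, with 0 of these 3 measures outside the range of the others. A difference shared within the run of sample numbers stays open: across these genes the deviations correlated over 0.1 with 2 of the 7 other arrays of that run (highest 0.327, mean -0.076) and with 5 of 14 arrays of the other runs (highest 0.484, mean 0.013). Noise of dim probes stays open as a part of it, since these genes had a median log2 level of 6.08 against 7.83 for all genes tested, but brighter genes such as SPATA13 (-1.58 at a level of 8.54) and GTF2A1 (-1.44) were off too. No biological explanation was tested, because the design names none for a single array.

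Enzalutamide lowered the androgen-induced list slightly at Dex 100 nM, by a mean of -0.10 with 18 of 25 genes lower. Without Dex 100 nM replicate 2 the mean was -0.114 ± 0.037 (standard error over the list's array means), which argues against that array as the cause. Relative to the median of all genes the list was at -0.089 in the main fit. It was at -0.0846 with median scaling, -0.0775 without background correction and -0.101 with the deposited values. This argues against a shift of all genes as the cause. The fit without background correction kept the quantile normalization, and the method of the deposited values is unknown. Only median scaling is thus known to be another scaling. Across the 549 DHT genes the enzalutamide change at Dex 100 nM had a negative slope on the DHT change in 9 of 9 pairs of arrays (mean -0.068, against -0.019 at Dex 10 nM and -0.89 with DHT itself), so a small part of the response to Dex 100 nM may pass through the pathway that enzalutamide blocks. With the Dex 10 nM change as a further term over 678 genes, its coefficient was also negative in 9 of 9 pairs (mean -0.058, and -0.039 for the DHT term), so a slightly weaker response of every Dex gene may contribute as well. Both stay open, as hypotheses found on these data. The 9 pairs cross the same 3 arrays of each group, so they are not independent results.

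Genes differed between Dex 100 nM and DHT in both directions. If the doses differed only in strength on 1 scale, genes raised by either hormone should lie on one side, but of those raised by DHT 37 were higher and 83 lower with Dex (rarer side 30.8%), and of those raised by Dex 100 nM 126 were higher and 21 lower (14.3%). Each set was picked on arrays that also enter this comparison, which favours its larger side, so only the rarer sides count against a single scale. Scaling is argued against by the 92.0% of the 337 genes that kept direction and call with median scaling over the genes tested, although median scaling over all probes called 212. A difference between androgen and glucocorticoid signalling in the genes driven, and genes that differ in their sensitivity to dose, were not tested and stay open at 1 nM DHT and 100 nM Dex.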

How the results depend on the processing

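Median scaling over the genes tested, robust eBayes and leaving out both arrays with the most deviating genes were chosen after the data were seen. No named gene's called change turned direction: of 476 values, the background, array weight, trend, deposited-value, robust and stricter-filter settings kept the direction and side of the threshold for 471, 463, 467, 463, 466 and 452 (of 453) values. Median scaling over all probes kept 401, median scaling over the genes tested 461, the mean of a gene's probes 438, every probe alone 448 (values of the kept probe), no filter 440, a 1.5-fold minimum 364 and only the groups compared 335. With 1 array left out, 2906 of 3360 values did so. The trend, robust, 1.5-fold, every-probe and only-the-groups-compared settings leave each log2 change as it was. They could change a call but could not turn a direction. With only the groups compared, which leaves fewer arrays to estimate the spread, counts of called genes were 290 for DHT, 102 for Dex 10 nM, 277 for Dex 100 nM, 0 for enzalutamide, 233 for enzalutamide with DHT against DHT, 14 between the Dex doses, 120 for Dex 100 nM against DHT, 57 and 168 for enzalutamide with Dex 10 and 100 nM against enzalutamide, and 126 for the difference in enzalutamide effect between Dex 100 nM and DHT; the median share of the Dex 10 nM response kept under enzalutamide was 0.782. A 1.5-fold minimum, which removes smaller changes by construction, gave 233, 101, 252, 1, 204, 42, 133, 73, 187 and 135 for the same comparisons in the same order, 123 genes shared by DHT and Dex 100 nM, and kept shares of 0.841 (Dex 10 nM) and 0.833 (Dex 100 nM). Median scaling over all probes gave 552 for Dex 10 nM, 212 for Dex 100 nM against DHT, 288 for enzalutamide with Dex 100 nM against enzalutamide, 1 for enzalutamide with Dex 10 nM against Dex 10 nM, 149 for the DHT interaction and 112 for the difference between Dex 100 nM and DHT, with kept shares of 0.0101 (DHT) and 0.0712 (Dex 10 nM) and a correlation of 0.769 between DHT and enzalutamide with Dex 100 nM; array weights gave 0.731 for the last. Median scaling over the genes tested gave 0 for enzalutamide, 1 for enzalutamide with Dex 10 nM and 1 with Dex 100 nM against the steroid alone. The deposited normalized values gave 1 for enzalutamide with Dex 100 nM against Dex 100 nM and 2 for each Dex interaction, and an intensity trend gave 2 for the former. The enzalutamide count of 2 was 0 with no background correction, no filter, the mean of probes, every probe alone, array weights and robust eBayes, and 1 with the stricter filter and the trend. Without the pair of arrays with the most deviating genes, there were 41 calls between the Dex doses, 220 for Dex 100 nM against DHT, 1 for the Dex 100 nM interaction and 131 for the difference between Dex 100 nM and DHT; Dex 100 nM against vehicle gave 449, of which 417 were among the 653. Except where stated, the cause was not tested. Leaving out 1 array at a time, counts ran from 406 to 440 (DHT), 176 to 212 (Dex 10 nM), 464 to 580 (Dex 100 nM), 0 to 2 (enzalutamide), 368 to 397 (enzalutamide with DHT against DHT), 0 to 1 (with Dex 10 or 100 nM against that dose), 45 to 81 (Dex doses), 208 to 258 (Dex 100 nM against DHT), and against enzalutamide 0 to 2 (with DHT), at most 132 and within 1.5 times of 139 (with Dex 10 nM) and 305 to 352 (with Dex 100 nM). Interactions ran from 182 to 206 (DHT), 0 to 1 (each Dex dose) and 156 to 181 (Dex 100 nM minus DHT), kept shares from 0.0194 to 0.0361 (DHT), 0.649 to 0.770 (Dex 10 nM) and 0.645 to 0.761 (Dex 100 nM), the overlap from 215 to 244 and the correlation from 0.741 to 0.757. Of 53 gene list calls, 32 held with an estimated correlation and 48 without the deviating pair of arrays. Over the 252 list tests fry, which asks whether a list's genes move one way and not whether they differ from other genes, called 104, among them all 53. Sample numbers fall in 3 runs that may or may not mark pairs. Deviations correlated at a mean of 0.077 within a run (35 of 84 pairs over 0.1) and of -0.0385 between runs. No comparison had all 3 of its within-run values over 0.1, so runs were not used as pairs. That rule does not exclude variation shared within runs. A replicate block by run gave 621, 335, 777 and 0 calls for DHT, Dex 10 nM, Dex 100 nM and enzalutamide and 52 of the 53 list calls, and within runs the kept shares were 0.021 to 0.023 (DHT), 0.60 to 0.71 (Dex 10 nM) and 0.65 to 0.73 (Dex 100 nM). A block by chip was not run. Signal over background limits genes such as KLK3 and PER1, which lay near the detection limit. Of the genes called with DHT, 187 had over 1 probe past the filter, and 73 of these had another probe called the same way. With Dex 100 nM 73 of 233 did. The calls of the others rest on the kept probe alone. Within either comparison no gene had probes called in both directions.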

Other observations

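In this part the test on NR3C1 probes was chosen after its values were seen, as was the way to weigh the spread in the first test on doses, whose bounds were set before.

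SCNN1G, the gamma subunit of the epithelial sodium channel, rose by 1.00 ± 0.13 on the log2 scale with Dex 10 nM and by 2.13 ± 0.13 with Dex 100 nM (adjusted p = 8.63e-10), and by 2.13 ± 0.13 with Dex 100 nM under enzalutamide. SCNN1A, its alpha subunit, rose 1.46-fold with Dex 100 nM (adjusted p = 1.2e-06; chosen after its values were seen). EMP1, detected on 2 of 3 vehicle arrays, rose by 1.39 ± 0.17 and 2.04 ± 0.17 with the Dex doses and was 0.16 ± 0.17 with DHT (adjusted p = 0.818). PNLIP, the pancreatic lipase gene, was not detected with vehicle, DHT or Dex 10 nM and rose at least 2.39-fold with Dex 100 nM and at least 3.01-fold under enzalutamide. PGLYRP2, a peptidoglycan-cleaving amidase, was not detected with vehicle and rose at least 2.45-fold and at least 3.24-fold with the Dex doses.

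The alpha-tubulin genes TUBA3C and TUBA3E were among the largest rises with DHT and both Dex doses. TUBA3E rose 4.61-fold with DHT, 6.95-fold with Dex 10 nM and 13.8-fold with Dex 100 nM (log2 3.78 ± 0.11), and 11.1-fold with Dex 100 nM under enzalutamide. TUBA3C rose 4.32-fold, 6.39-fold and 12.1-fold with the 3 steroid treatments. The probes of TUBA3C, TUBA3D and TUBA3E read near-identical copies, so which copy rose is uncertain; 2 probes of TUBA3D gave 2.16 and 0.58 on the log2 scale with DHT. TRIM49D1, detected on 2 of 3 arrays with Dex 10 nM and higher by 1.37 ± 0.16 at the higher Dex dose, belongs to a similar family of copies.

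A first hypothesis was that genes higher at Dex 100 nM than at 10 nM (75 genes, median difference 0.58 on the log2 scale) owed this to activation, by the higher dose, of the pathway that enzalutamide blocks. Enzalutamide would then have lowered them by over 0.29 at Dex 100 nM. Their median change with enzalutamide was -0.0945 (highest -0.066 over the 9 pairs of arrays, SD 0.024), and a fall smaller than 0.146 had been set as evidence against it. The median lay inside that bound by more than the SD, but 1 of the 9 pairs reached it at -0.146, and the choice of genes on the Dex 100 nM arrays biases towards a fall. The 9 pairs cross the same 3 arrays of each group, so they are not independent and their SD is not a standard error. The same genes had a median of -0.61 when enzalutamide was added to DHT. A rule that asked all 9 pairs to lie inside the bound left the hypothesis open, and the rule used here was chosen after the value was seen. The median alone argues against that pathway as the main cause of the dose difference. That pair, the late choice of rule and the arrays shared between pairs are limits.

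A second one was that the genes higher at the higher dose are more often DHT genes than other Dex genes. Of 73 such genes that also rose with Dex 100 nM against vehicle, 44 rose with DHT, against 125 of the 298 others (odds ratio 2.10, two-sided Fisher's exact p = 0.0058, across genes, which are not independent). The DHT and Dex 100 nM changes share the vehicle arrays, so the odds ratio may in part come from them. The 73 and the 298 genes were not matched on the size or precision of their Dex change. A difference in how easily they are called may therefore contribute too.

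The third concerned NR3C1, which fell with DHT and both Dex doses on 1 probe, detected on all 24 arrays. If all its transcripts had fallen, the other probe past the detection filter should have fallen by over 0.5 of that, and it moved by a share of 0.0418 (-0.05 ± 0.16 with Dex 100 nM). That probe was detected on only 3 arrays and another on 0, so both lie near background and cannot decide. The change may belong to all NR3C1 transcripts or to some of them.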
